A study of Mus musculus with 18 samples.

How the data were processed

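RNA was measured in whole testes of 18 adult hypogonadal (hpg) male mice, 10 weeks old, which lack gonadotrophin-releasing hormone and so have very little circulating follicle-stimulating hormone (FSH) or luteinising hormone. Per the series' design text, treated mice received recombinant FSH subcutaneously, 8 IU in a volume of 0.2 ml, at 12 h intervals for 12, 24 or 72 h, and testes were taken 1 h after the final dose. Untreated hpg males of the same age were the controls. The groups held 7 controls, 4 mice at 12 h, 3 at 24 h and 4 at 72 h, and each mouse gave 1 array, so the spread between arrays includes the spread between animals.

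Per the labels' protocols, 8 micrograms of total RNA per mouse was turned into biotin-labelled cRNA and hybridised to an Affymetrix MOE430A mouse array, which has 1 colour. The authors deposited 1 table of expression values per probe set, and the submitters' processing notes name RMA and GCRMA, 2 methods that correct the background, normalise between arrays and combine the probes of a set. Which of them made the deposited log2 values, their versions and the probe set definition used are not given in the sources used here. The deposited values were taken as log2 from their range, 1.04 to 15.2, since the table states no scale, base or centring. Array medians lay between 4.44 and 4.63 and were close without being equal. For arrays, precision is limited by their number, and a low value is at the floor of the array and gives only a bound on the transcript.

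The table held 22690 probe sets. The 64 control probe sets were left out of all tests, and 22626 were tested without a filter on low values. The platform annotation paired 20380 of these with 1 gene symbol, 691 with several and 1555 with none. Only probe sets with 1 symbol were named, and they represented 12393 genes. The entrez identifiers of 20351 probe sets were found in a current gene table, which changed 0 symbols. No pair of arrays was a duplicate, as the highest correlation between 2 arrays was 0.997 and the lowest 0.945.

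Each probe set was fitted with limma 3.58.1 in R 4.3.3, with a mean per group over all 18 arrays and moderated variances (lmFit and eBayes, two-sided, 14 residual degrees of freedom). Each time was compared with the 7 controls, each pair of times was compared directly, and a moderated F test asked for a change at any time. P values were adjusted by the Benjamini-Hochberg method over the 22626 probe sets, and a call needed an adjusted p below 0.05. Fold changes are differences of log2 means with their standard errors (SE). These values understate the change of transcripts near the floor.

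The groups, the tests, the gene lists and the rule for named genes were fixed before the data were examined. Named are, for each time, the 12 genes with the largest rise and the 8 with the largest fall among called probe sets with 1 symbol whose treated arrays all lay on the same side of the control mean, using the probe set with the highest mean for each gene. For each time difference the 4 largest in each direction were named, for each gene list up to 4 members with the smallest p at the time with most members called, and for each time pattern 5 genes. Other list members are given as examples and were chosen after their values were seen. Fshr, Inha, Inhba, Inhbb, Amh, Star, Cyp11a1, Cyp17a1, Hsd3b1, Hsd17b3, Kit, Kitl, Stra8, Dazl and Sycp3 were to be reported whatever their values. Lhcgr, Trf, Cyp19a1, Insl3 and Gnrh1 were chosen too and were not analysed here.

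A total of 28 gene lists with 622 genes, 529 of them measured, covered FSH regulated genes, immediate early genes, cholesterol and lipid metabolism, glucose use, matrix, junctions, retinoids, transforming growth factor signalling, cell cycle and G1 cyclins, chaperones, heat shock, interferon response and ribosomes, and markers of Sertoli, Leydig, peritubular myoid, endothelial, red blood, fat and epididymal cells, macrophages, spermatogonia, meiotic cells, pachytene spermatocytes and spermatids. They were tested on 1 probe set per gene with limma's camera, which compares a list with all other genes, at a preset correlation between genes of 0.01, adjusted over the 28 lists. Each test was repeated with a correlation estimated for each list. Of the shifts in a comparison with the controls, only the cholesterol list at 12 h held with an estimated correlation. Of the shifts between times, the cholesterol list between 72 h and 12 h did.

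The arrays fell into 2 technical sets, described with the results. The set was added as a block to every fit, and the fit was repeated within each set alone. These settings, and quantile normalisation and leaving out arrays for the agreement of times, were chosen after seeing the data. In the blocked fit, with 13 residual degrees of freedom, the fold change at each time equals the difference from the controls of the same set of arrays, so the blocked value is also the within-set value and the settings differ only in the error they use.

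Comparisons of times with the shared controls were set beside simulated unchanged groups against the same 7 controls, beside the overlap of independent lists and beside 100 splits of the controls between the times, drawn from 35 distinct subsets. Other settings were quantile normalisation, median centring, array weights, a variance trend with robust moderation, a filter on low values, a minimum fold change, an offset of 16 on the linear scale, other probe sets of a gene, the replicate number as a block, only the arrays compared, and leaving out each array in turn.

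The fits were tested on simulated data with 200 of the 22626 probe sets changed. Changes of 1 on the log2 scale were recovered at 83.6% for 12 h, 83.6% for 24 h and 85.1% for 72 h, and changes of 0.5 at 52.2%, 46.3% and 53.7%. False calls made up 8.72%, 7.32% and 4.79% of the calls. With a shift between array sets added and no block these were 9.88%, 20.6% and 9.3%, and 7.27%, 4.76% and 5.13% with the block. In that simulation without a block 1101 probe sets were falsely called between 24 h and 12 h, against 1 with the block. A list shifted by 1 on the log2 scale was called in the simulated 12 h comparison.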

Results

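Testicular transcripts were measured in hpg males after 12, 24 or 72 h of FSH treatment, in 4, 3 and 4 mice, and in 7 untreated hpg males. The comparisons address how testicular transcript levels respond to FSH over time in an animal that lacks its own gonadotrophins. FSH acts through a receptor on Sertoli cells, the somatic cells that line the seminiferous tubules, whereas Leydig cells, which make androgens, lie between the tubules. All values are log2 expression per probe set as deposited, with fold changes against the mean of the 7 controls unless a time difference is named. The median of an array lay between 4.49 and 4.52 at 12 h, between 4.44 and 4.51 at 24 h, at most 4.55 at 72 h and between 4.48 and 4.63 in controls.

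The arrays formed 2 technical sets that crossed the groups. Probe sets for the Dap transcript, a bacterial RNA added as a spike-in, read 8.00 to 8.92 on 12 arrays and 2.74 to 3.30 on the other 6. The 12 spiked arrays were all those of 12 h and 72 h and controls 4 to 7, and the 6 unspiked arrays were those of 24 h and controls 1 to 3. Probe sets for 18S ribosomal RNA read 3.35 to 3.70 on the spiked arrays and 9.07 to 11.7 on the unspiked ones, and the actin 3 prime minus 5 prime difference was 1.22 to 1.82 and 0.82 to 1.10. Untreated controls alone differed between the sets at 2107 probe sets, 1049 higher and 1058 lower on the unspiked arrays. Values against the 7 controls without a block carry part of this difference at every time, since the controls lie in both sets. With the block 60.6%, 32.6% and 60.3% of the calls at 12, 24 and 72 h kept call and direction.

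**Figure D1:**
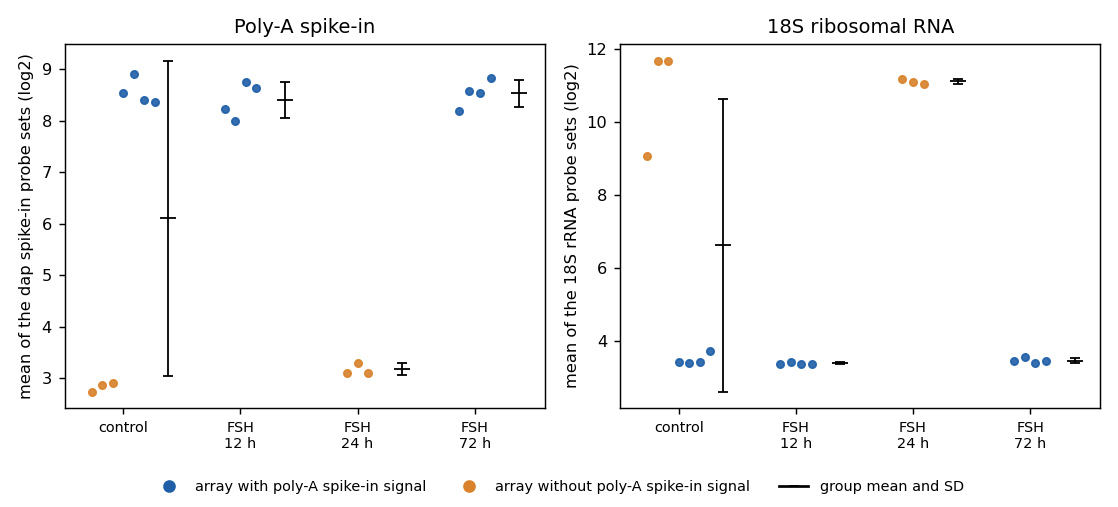
Mean log2 level of the Dap spike-in probe sets and of the 18S ribosomal RNA probe sets on each of the 18 arrays, by group. The 12 h and 72 h arrays and 4 of the 7 controls have Dap at 8.00 or above and 18S at 3.70 or below, and the 24 h arrays and the other 3 controls have Dap at 3.30 or below and 18S at 9.07 or above.

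After 12 h of FSH the largest rise was in Aqp5, a water channel, which rose 18.5-fold, by 4.21 ± 0.26 (log2, SE, n = 4 against 7), from 3.15 ± 0.26 (SD) in controls to 7.36 ± 0.49 (limma adjusted p = 7.93e-08). Fabp5, a fatty acid binding protein, rose 13.1-fold, Wif1, a secreted Wnt inhibitor, by 3.46 ± 0.20, Tubb3, a beta tubulin, 9.26-fold, and Col4a1, a basement membrane collagen, 8.48-fold. Dmkn, a secreted protein, rose 17.2-fold (4.11 ± 0.52) from 2.27 to 2.39 in controls, near the floor, so its fold may be understated. Pappa, a protease that cleaves binding proteins of insulin-like growth factors, rose 8.45-fold, Tesc 8.47-fold, Hs3st1 6.64-fold and Esyt3 2.60 ± 0.27 on the log2 scale. The largest falls were in Rin2, a regulator of Rab proteins, which was 7.07-fold lower (-2.82 ± 0.16), Tmem37 (7.04-fold lower), Myh8 (6.02-fold lower) and Slc40a1, the cellular iron exporter (5.91-fold lower). Also lower were Coq8a (-2.55), Ddit4l, an inhibitor of mTOR signalling (-2.45), Crebrf (-2.42) and Rgs11, a regulator of G protein signalling (5.28-fold lower). Another probe set of Coq8a gave -0.25 (adjusted p = 0.403).

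At 12 h, 1640 probe sets of 1206 genes were called, 1066 higher and 574 lower, and 418 of them changed at least 2-fold. With the array set as a block 1211 were called, 723 higher and 488 lower, and 994 were called in both fits, all in the same direction. All 20 named genes stayed called with the block and within the spiked set alone, where Aqp5 rose by 4.17 and Cyp17a1 by 2.86. That fit called 1356 probe sets.

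Inha, which encodes the inhibin alpha chain and is a product of Sertoli cells, rose alike at each time. Its level was 10.06 ± 0.18 (SD) in controls, 11.87 ± 0.21 at 12 h, 11.90 ± 0.18 at 24 h and 11.94 ± 0.06 at 72 h, or 3.50-fold, 3.58-fold and 3.68-fold higher (adjusted p = 5.46e-08, 1.05e-07 and 3.61e-08). Differences between times were 0.03 ± 0.13, 0.04 ± 0.13 and 0.07 ± 0.12, with adjusted p of 0.859, 0.82 and 0.989. Inhbb, the inhibin beta B chain, rose by 0.84 ± 0.15 at 12 h and 0.71 ± 0.15 at 72 h, and was -0.01 ± 0.16 at 24 h. It was lower at 24 h than at 12 h (-0.85, adjusted p = 0.00375), a difference not called with the block (-0.87, adjusted p = 0.136). A dimmer probe set of Inhbb gave -0.04 at 72 h. Inhba was 0.41 ± 0.15, 0.57 ± 0.17 and 0.29 ± 0.15, called at 24 h alone and not with the block there (0.46, adjusted p = 0.129).

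Star, Cyp17a1 and Cyp11a1 were higher after 12 h and 24 h, while Hsd3b1 and Hsd17b3 were not called. Star, which carries cholesterol into mitochondria, rose 6.39-fold at 12 h and 4.95-fold at 24 h (2.68 ± 0.25 and 2.31 ± 0.27, adjusted p = 4.75e-06 and 4.01e-05). Cyp17a1, the hydroxylase and lyase that leads to androgens, rose 10.6-fold and 14.9-fold (3.41 ± 0.44 and 3.89 ± 0.49, adjusted p = 0.000146 and 7.17e-05). Cyp11a1, the side-chain cleavage enzyme that starts steroid synthesis, rose by 2.35 ± 0.63 at 12 h (adjusted p = 0.033) and 14.7-fold at 24 h (3.88 ± 0.69, adjusted p = 0.00115). With the array set as a block Star rose 5.79-fold and 5.64-fold, Cyp17a1 by 2.86 and 4.62 and Cyp11a1 by 4.03 at 24 h, all called, while Cyp11a1 at 12 h was 2.24 ± 0.73 and not called (adjusted p = 0.104). Without 12 h replicate 1, 2 or 4, or without control 1, 2, 3, 4 or 7, the 12 h call of Cyp11a1 was also lost. Its values were then 1.91, 2.29, 2.53, 2.32, 2.32, 2.35, 2.29 and 2.32. At 72 h Star was 1.01 ± 0.25 (adjusted p = 0.0163), but 0.87 with the block (adjusted p = 0.083) and 0.98 without 72 h replicate 2 or 3 (adjusted p = 0.0557 and 0.0542). A second probe set of Star gave 1.25 at 72 h and stayed called with the block (adjusted p = 0.00567, block 1.08 and 0.0351), and another, dimmer one was not called (adjusted p = 0.293). At that time Cyp17a1 was 0.95 ± 0.44 (adjusted p = 0.248) and Cyp11a1 1.66 ± 0.63 (adjusted p = 0.136). Hsd3b1 was -0.27, -0.44 and -0.24 and Hsd17b3 0.46, 0.06 and 0.33, none of them called. The list of Leydig cell markers as a whole was not called as shifted (adjusted p = 0.176, 0.255 and 0.411, block 0.0763, 0.194 and 0.456), with 5, 7 and 2 of its 15 measured members higher and 0, 2 and 1 lower, or 6, 7 and 3 higher and 3, 2 and 1 lower adjusted over the list alone. Its median fold change was -0.06 at 12 h and 0.00 at 72 h where its mean was 0.47 and 0.22, so the few strong members carry the mean.

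**Figure D2:**
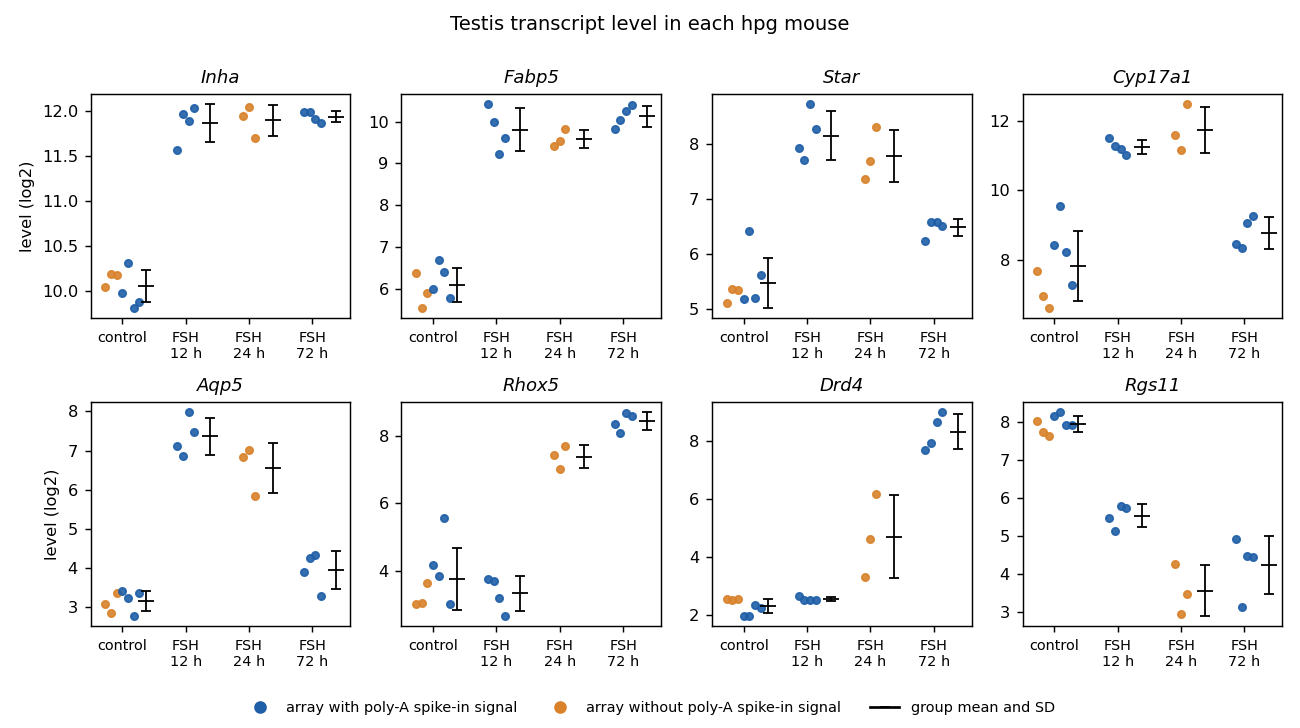
Log2 level of Inha, Fabp5, Star, Cyp17a1, Aqp5, Rhox5, Drd4 and Rgs11 on each array, by group, with the group mean and SD as a bar and the 2 array sets in different colours. Inha and Fabp5 are higher at all 3 times, Star, Cyp17a1 and Aqp5 are highest at 12 h or 24 h, Drd4 and Rhox5 are highest at 72 h, and Rgs11 is lower at all 3 times.

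Genes of cholesterol synthesis and uptake rose together at 12 h. Of 21 measured members 13 rose and 0 fell, 14 and 0 adjusted over the list alone. Dhcr7, which makes cholesterol in the last step of one branch of the pathway, rose 2.81-fold (1.49 ± 0.12, n = 4 against 7, adjusted p = 2.05e-06), Sqle, the squalene epoxidase, by 1.46 ± 0.14, Fdps by 1.28 ± 0.13 and Nsdhl by 0.92 ± 0.10, while a second probe set of Fdps near the floor read -0.03. The list was shifted upwards against all other genes (camera adjusted p = 8.06e-16), also with the array set as a block (3.06e-15) and with an estimated correlation (adjusted p = 0.000867). At 24 h 7 members rose and 0 fell, 7 and 0 adjusted over the list alone, without a shift of the list (adjusted p = 0.123, block 0.069). At 72 h 4 rose and 0 fell, 6 and 0 adjusted over the list alone, with a shift (adjusted p = 0.00102, block 0.00173) that was not called with an estimated correlation (adjusted p = 0.139). Between 12 h and 72 h the list fell (adjusted p = 9.1e-12, block 8.07e-11, and adjusted p = 0.00381 with an estimated correlation), with 9 members lower and 1 higher at 72 h, 14 and 2 adjusted over the list alone. With the block 10, 5 and 4 members rose and 1, 0 and 0 fell at 12, 24 and 72 h, and 9 were lower and 2 higher at 72 h than at 12 h.

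**Figure D3:**
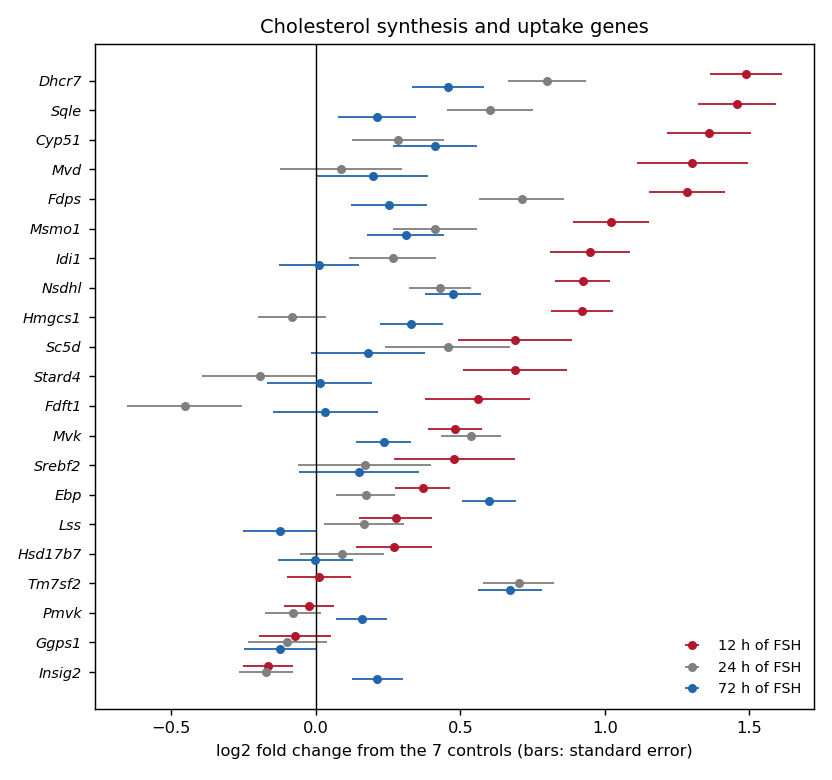
Log2 fold change against the 7 controls, with its SE, of each of the 21 measured genes of cholesterol synthesis and uptake at 12, 24 and 72 h. Values at 12 h reach 1.49 in Dhcr7 and 1.46 in Sqle.

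A further 5 lists were shifted at 12 h. Of 22 measured genes that textbooks describe as FSH regulated, 9 rose and 0 fell, 10 and 3 adjusted over the list alone (adjusted p = 4.13e-05, block 0.000569, and adjusted p = 0.0693 with an estimated correlation). Star, Cyp11a1, Inhbb, Fshr, Shbg and Rhox5 of this list are also in the Leydig or Sertoli lists. With the block 7 members of this list rose and 2 fell at 12 h, 9 and 1 at 24 h and 7 and 2 at 72 h. Among 15 markers of peritubular myoid cells, the contractile cells around the tubules, 5 rose and 0 fell, 8 and 0 adjusted over the list alone, such as Tpm2 (1.12 ± 0.16), Myl9 (0.61 ± 0.12) and Flna (0.59 ± 0.12), while Cnn1 (1.30 ± 0.28) was not called with the block (1.05, adjusted p = 0.0548). This list was called (adjusted p = 1.88e-05, block 1.27e-05), but not with an estimated correlation (adjusted p = 0.119). Among 27 genes of collagens, laminins and matrix remodelling 8 rose and 1 fell, 11 and 1 adjusted over the list alone, with Col4a2 at 1.90 ± 0.18 and Serpinh1, a collagen chaperone, at 0.89 ± 0.15 (list adjusted p = 4.46e-05, block 0.000925, and adjusted p = 0.345 with an estimated correlation). Cell cycle genes were shifted down with 0 of 32 higher and 2 lower, also 0 and 2 adjusted over the list alone (adjusted p = 0.00158, block 0.000925, and adjusted p = 0.321 with an estimated correlation). Meiotic prophase genes were shifted down with 0 of 21 higher and 2 lower, also 0 and 2 adjusted over the list alone (adjusted p = 0.0316, block 0.00354, and adjusted p = 0.613 with an estimated correlation), with Dmc1, the meiotic recombinase, at -0.65 ± 0.13. The meiotic list was not called without 12 h replicate 4 or controls 3, 4 or 7 (adjusted p = 0.188, 0.0702, 0.079 and 0.073). With the block 3 myoid markers rose and 0 fell, 5 and 1 matrix genes, 0 and 0 cell cycle genes and 0 and 2 meiotic genes.

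After 24 h of FSH, Cyp17a1, Cyp11a1 and Rhox5 had the largest rises. Rhox5 is an X-linked homeobox gene of Sertoli cells that responds to androgen, and it rose 12.2-fold from 3.76 ± 0.92 (SD) to 7.37 ± 0.34 (3.61 ± 0.44 SE, n = 3 against 7, adjusted p = 6.1e-05). Fabp5 (11.3-fold), Aqp5 (10.6-fold), Tubb3 (8.53-fold), Tesc (8.36-fold) and Pappa (4.91-fold) were again higher. Slc38a5, a glutamine transporter (5.89-fold), Fah, an enzyme of tyrosine breakdown (5.42-fold), and Drd4, a dopamine receptor (5.23-fold), also rose. Rgs11 was 20.7-fold lower (-4.37 ± 0.32, adjusted p = 5.36e-07). Igfbp3, a binding protein of insulin-like growth factors, was 11.7-fold lower, Rin2 10.4-fold lower and Slc40a1 8.64-fold lower. Itga9, an integrin, was 12.8-fold lower, Dapk1 by -3.67 ± 0.31, Antxr1 by -3.00 ± 0.24 and Myh6, a heart muscle myosin, 7.98-fold lower. With the block Rhox5 rose by 4.13 ± 0.48, and Rgs11 was at -4.21 ± 0.38, Igfbp3 at -3.21 ± 0.50, Slc40a1 at -3.67 ± 0.21, Itga9 at -3.36 ± 0.29 and Dapk1 at -3.05 ± 0.22. Dimmer probe sets of Itga9, Antxr1 and Myh6 gave 0.44, 0.26 and 0.69 at 24 h, against the direction of the brighter ones. These rises were called without a block (limma adjusted p = 0.0389, 0.00468 and 0.00602), so called probe sets of these genes conflict. One more probe set of Itga9 gave -0.15.

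The call count at 24 h depended on the array set. Without a block 8137 probe sets were called, 5283 higher and 2854 lower (64.9% higher), and 1155 changed at least 2-fold. With the block 3023 were called, 1381 higher and 1642 lower (45.7% higher), and 2651 probe sets, 32.6% of the 8137, were called in both fits in the same direction. Within the unspiked set alone, 3 arrays against 3, 393 were called, 152 higher and 241 lower, and without 24 h replicate 2 the fit on all arrays called 3910. All 20 named genes stayed called with the block and 17 within the unspiked set alone, where Cyp11a1 (4.03, adjusted p = 0.0827), Slc38a5 (2.90, adjusted p = 0.12) and Drd4 (2.16, adjusted p = 0.237) were not.

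Among markers of spermatogonia, the dividing germ cells, more fell than rose at 24 h. The list as fixed also held Kitl, which encodes the ligand of the receptor Kit and is not a marker of these cells. Kitl is in the FSH regulated list too. Of 23 measured markers 2 rose and 9 fell, also 2 and 9 adjusted over the list alone, such as Sall4 (-1.37 ± 0.16, n = 3 against 7), Elavl2 (-1.50 ± 0.26), Stra8, a gene of the entry to meiosis (-1.11 ± 0.17), and Tex14 (-0.94 ± 0.14). With the block Sall4 was at -1.10 ± 0.14, Elavl2 at -1.11 ± 0.26, Stra8 at -1.06 ± 0.20 and Tex14 at -0.88 ± 0.16. A dim second probe set of Sall4 gave 0.02 and 2 dim ones of Elavl2 gave 0.02 and 0.20, while 2 brighter ones of Elavl2 gave -0.82 (adjusted p = 0.0323) and -0.26 (adjusted p = 0.425). With the block 0 markers rose and 6 fell. The list was shifted down (adjusted p = 0.0327, block 0.021, but adjusted p = 0.242 with an estimated correlation), and the call was lost without 24 h replicate 1 or 2 or controls 1 or 3 (adjusted p = 0.051, 0.0589, 0.0569 and 0.0626). Kit, the stem cell factor receptor, fell by 1.53 ± 0.27 (adjusted p = 0.00116, block -1.39 and 0.0126), and was -0.18 ± 0.25 at 12 h and -0.67 ± 0.25 at 72 h (adjusted p = 0.729 and 0.122). A second probe set of Kit was -0.24 at 24 h (adjusted p = 0.616, block -0.86 and 0.08). Within the unspiked set alone Kit (adjusted p = 0.115), Stra8 (0.0967), Elavl2 (0.092) and Tex14 (0.098) were not called. Dazl was -0.25, -0.31 and -0.38 and Sycp3 -0.06, -0.25 and 0.14 at the 3 times, with no call.

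The FSH regulated list was also shifted up at 24 h, with 10 members higher and 3 lower, 11 and 3 adjusted over the list alone (adjusted p = 0.0146, block 0.00148, and adjusted p = 0.345 with an estimated correlation). Fshr, the FSH receptor itself, fell at 24 h from 6.11 ± 0.54 (SD) to 4.35 ± 0.48 (-1.76 ± 0.28 SE, adjusted p = 0.000517), and was -0.70 ± 0.26 at 12 h and -0.72 ± 0.26 at 72 h (adjusted p = 0.127 and 0.107). With the array set as a block Fshr was called lower at all 3 times, by -1.10 ± 0.20, -1.24 ± 0.23 and -1.11 ± 0.20 (adjusted p = 0.00327, 0.00274 and 0.0031), though not at 24 h within the unspiked set alone (adjusted p = 0.11). Markers of the epididymis and efferent ducts were shifted up with 7 of 9 higher and 0 lower, 8 and 0 adjusted over the list alone (adjusted p = 0.0311), or 2 and 0 with the block. Their values lay near the floor, as with Adam28 at 2.69 against 2.46 in controls, and the shift was not called with the block (adjusted p = 0.069), with an estimated correlation (adjusted p = 0.679) or without 24 h replicate 2 (adjusted p = 0.0589). Amh read 1.57 in controls and 1.56, 1.59 and 1.56 after FSH, at the floor.

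After 72 h of FSH, Drd4 had the largest rise of any time, 64.7-fold from 2.30 ± 0.25 (SD), near the floor, to 8.32 ± 0.60 (6.02 ± 0.38 SE, n = 4 against 7, adjusted p = 1.26e-07), Slc38a5 29.9-fold (4.90 ± 0.37) and Rhox5 25.3-fold (4.66 ± 0.40). A dimmer probe set of Drd4 rose by 2.83 at 72 h (adjusted p = 3.07e-05) and gave 0.02 at 24 h (adjusted p = 0.965). Eppin, a protease inhibitor made by Sertoli cells and the epididymis, rose 15.5-fold (3.95 ± 0.51, and 3.11 with the block), and Tsx, an X-linked gene of Sertoli cells, 6.44-fold (2.69 ± 0.33). Fabp5 (16.4-fold), Tubb3 (9.27-fold), Klk1b24, a kallikrein (7.91-fold), Fah (2.97 ± 0.21 on the log2 scale), Hdc, which makes histamine (7.74-fold), Slc7a4 (2.68 ± 0.43) and St8sia2, a sialyltransferase (5.74-fold), also rose. Rgs11 was 13.0-fold lower (-3.70 ± 0.29), Igfbp3 11.4-fold and Slc40a1 10.1-fold lower. Rin2 was 8.33-fold, Tmem37 7.25-fold and Clca3a1 5.69-fold lower, and Ifitm1 changed by -2.42 ± 0.32 and Spsb1 5.23-fold lower. Dim other probe sets of Clca3a1 (-0.09) and Spsb1 (-0.13, -0.33 and -0.10) were not called, and of 2 for Slc7a4 one was (1.67, adjusted p = 0.0029) and one was not (0.48).

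At 72 h, 1915 probe sets of 1436 genes were called, 1228 higher and 687 lower, and 479 changed at least 2-fold. With the block 1388 were called, 822 higher and 566 lower, with 1155 called in both fits in the same direction. All 20 named genes stayed called with the block and within the spiked set alone, where Drd4 rose by 6.19 and Rgs11 fell by 3.82. That fit called 1612 probe sets.

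At 72 h 8 lists were shifted up, among them the cholesterol list given above. Of 30 Sertoli cell markers 9 rose and 1 fell, 9 and 2 adjusted over the list alone, with Shbg at 1.41 ± 0.16, Hopx at 1.39 ± 0.12 and Lgals1 at 1.24 ± 0.14 (list adjusted p = 0.00924, block 0.000957, and adjusted p = 0.166 with an estimated correlation). The FSH regulated list had 8 higher and 0 lower, 9 and 2 adjusted over the list alone (adjusted p = 7.88e-06, block 8.2e-05, and adjusted p = 0.0744 with an estimated correlation), with Igf1 at 2.10 ± 0.26. Of 27 matrix genes 12 rose and 1 fell, 17 and 1 adjusted over the list alone (adjusted p = 7.88e-06, block 0.000285, and adjusted p = 0.249 with an estimated correlation), with Col4a2 at 1.18 ± 0.18. Of 19 genes of glucose uptake, glycolysis and lactate 7 rose and 1 fell, 8 and 2 adjusted over the list alone, with Pgk1 at 1.32 ± 0.22 and Slc16a3, a lactate transporter, at 1.21 ± 0.24 (list adjusted p = 0.0124, block 0.0452, and adjusted p = 0.139 with an estimated correlation). Of 21 genes of endoplasmic reticulum chaperones 5 rose and 1 fell, 8 and 1 adjusted over the list alone, with Calr at 0.57 ± 0.11 and Hsp90b1 at 0.62 ± 0.17 (list adjusted p = 0.0306, block 0.0111, adjusted p = 0.166 with an estimated correlation, and adjusted p = 0.097 without 72 h replicate 4). Of 21 macrophage and antigen presentation markers 5 rose and 0 fell, 7 and 0 adjusted over the list alone, such as Cd68 (1.63 ± 0.22), Fcer1g (1.34 ± 0.23) and Mrc1 (0.92 ± 0.15). These genes stayed called with the block, but the list did not (adjusted p = 0.00529, block 0.136, and adjusted p = 0.426 with an estimated correlation). Of 19 genes of ribosome biogenesis 5 rose and 1 fell, 6 and 1 adjusted over the list alone, with Nhp2 at 1.12 ± 0.10 (list adjusted p = 0.0265, block 0.133, adjusted p = 0.249 with an estimated correlation, and adjusted p = 0.0515 without control 3). With the block 9 Sertoli markers rose and 1 fell, 8 and 1 matrix genes, 3 and 1 glucose genes, 5 and 1 chaperones, 3 and 1 macrophage markers and 4 and 0 ribosome genes.

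Shifted down at 72 h were 4 lists. Spermatogonia markers had 0 higher and 4 lower, 0 and 6 adjusted over the list alone (adjusted p = 0.0093, block 0.00454, and adjusted p = 0.0932 with an estimated correlation), with Stra8 at -0.99 ± 0.15 and Sall4 at -0.82 ± 0.15. Of 19 genes of retinoid metabolism and signalling 0 rose and 3 fell, 0 and 6 adjusted over the list alone (adjusted p = 0.0093, block 0.00839, and adjusted p = 0.166 with an estimated correlation). Of 31 genes of transforming growth factor beta, activin and bone morphogenetic protein signalling 1 rose and 2 fell, 2 and 4 adjusted over the list alone. Tgfb1 rose by 2.06 ± 0.20 and Tgfb3 fell by 1.41 ± 0.19, and the list was called (adjusted p = 0.0377, block 0.0452), but not with an estimated correlation (adjusted p = 0.321) or without 72 h replicate 1 or controls 1, 4 or 5 (adjusted p = 0.0538, 0.0504, 0.066 and 0.096). The interferon response list of 14 genes was shifted down (adjusted p = 0.0124, block 0.00096, and adjusted p = 0.249 with an estimated correlation) with 0 members called in either direction, also 0 adjusted over the list alone, though with the block 3 members fell. With the block 0 spermatogonia markers were higher and 3 lower, 0 and 1 retinoid genes, and 1 and 1 genes of the transforming growth factor list.

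**Figure D4:**
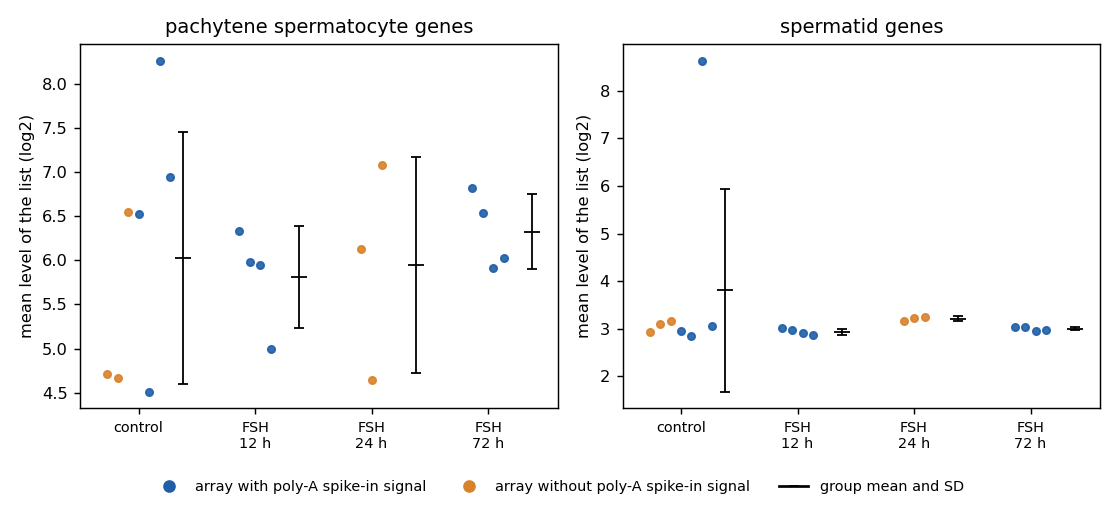
Mean log2 level of the pachytene spermatocyte list and of the spermatid list on each array, by group. Control 6 has a spermatid mean of 8.63, against 2.85 to 3.26 on the other 17 arrays, and a pachytene mean of 8.27, against 4.51 to 7.08.

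The lists of pachytene spermatocyte genes and spermatid genes were not called as shifted at any time without a block (adjusted p = 0.579, 0.669 and 0.8, and 0.114, 0.417 and 0.0989). For spermatid genes this depends on single arrays, as their list was called at 24 h without control 6 (median 0.12, adjusted p = 0.0103, against a median of -0.64 with it) and at 72 h without control 1 or 2 (medians -0.95, adjusted p = 0.0487 and 0.0413). Control 6 carried spermatid transcripts at a mean of 8.63, against 2.85 to 3.26 on the other 17 arrays. With the array set as a block the spermatid list was shifted down at 12 h (adjusted p = 0.00285) and 72 h (adjusted p = 0.00454), the 2 times whose set of arrays holds that control. The adjusted p was 0.56 and 0.628 with an estimated correlation, and no member was called. The pachytene list was also called down at 12 h with the block (adjusted p = 0.0494), but not with an estimated correlation (adjusted p = 0.695).

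Between 72 h and 12 h, which lie in the same set of arrays, Drd4 was 54.6-fold higher at 72 h (5.77 ± 0.43, n = 4 against 4, adjusted p = 8.28e-06), Rhox5 34.0-fold (5.09 ± 0.45), Eppin 16.7-fold (4.06 ± 0.57) and Slc7a4 11.7-fold higher. Aqp5 was 10.7-fold lower (-3.42 ± 0.29), and Crym, a thyroid hormone binding protein, differed by -2.78 ± 0.30, Tnfrsf12a by -2.74 ± 0.30 and Dmkn by -2.76 ± 0.59. Cyp17a1 (-2.46 ± 0.50, adjusted p = 0.018), Star (-1.66 ± 0.28, adjusted p = 0.00475) and Kitl, the ligand of Kit (-0.70 ± 0.15, adjusted p = 0.027), were lower at 72 h than at 12 h. Kitl had risen by 0.96 ± 0.14 at 12 h (adjusted p = 0.000303) and was 0.04 ± 0.15 and 0.26 ± 0.14 at 24 h and 72 h. In this comparison 423 probe sets differed, 246 higher and 177 lower, and 535 with the block, 410 of them in both fits. Array weights gave 1569, 806 higher and 763 lower. The count of the fit without weights was 212, 217, 246 and 276 without 12 h replicate 3, 12 h replicate 4, 72 h replicate 2 or 72 h replicate 3. The calls of Dmkn, Cyp17a1 and Kitl were lost without 12 h replicate 3 (adjusted p = 0.0902, 0.0544 and 0.0717), 72 h replicate 1 (0.0741, 0.0537 and 0.0864) or 72 h replicate 2 (0.0643, 0.0641 and 0.0643), and those of Dmkn and Kitl also without 12 h replicate 4 (0.0574 and 0.102) or 72 h replicate 3 (0.0634 and 0.0641).

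Comparisons of 24 h with the other times cross the sets of arrays. Rhox5 was higher at 24 h than at 12 h by 4.03 ± 0.49 (block 4.95, adjusted p = 0.00256), and Drd4 was higher at 72 h than at 24 h by 3.63 ± 0.46 (block 4.03, adjusted p = 0.0181). Itga9 (-3.47, block -2.91), Dapk1 (-2.89, block -1.80) and Myh6 (-3.58, block -3.29) were lower at 24 h than at 12 h, and Itga9 (2.68, block 2.12) and Dapk1 (2.77, block 1.68) higher at 72 h than at 24 h. Cyp17a1 was lower at 72 h than at 24 h by -2.94 ± 0.54 (block -4.22, adjusted p = 0.00843), as was Aqp5 (-2.62, block -2.72). Other large differences were not kept: Sdc4 read 10.84 at 24 h, 5.44 at 12 h and 5.50 at 72 h, and its differences of 5.40 and -5.34 became -0.61 and 0.67 with the block. Rpl27a (3.87 and -3.78, block 0.16 and -0.07), Trim35 (2.58, block 0.54) and Malat1 (-2.97, block -1.32) between 24 h and 12 h or 72 h, and Myh6 between 72 h and 24 h (3.43, block 3.15, adjusted p = 0.0673), were not called with the block. Without a block 9098 probe sets differed between 24 h and 12 h, 67% of them higher, and 7001 between 72 h and 24 h, 38.1% higher, and quantile normalisation gave 51.8% and 46.4% higher. With the lowest 50% of probe sets left out 22.3% and 79.7% were higher. With the block 198 and 84 were called, 35.9% and 57.1% of them higher, of which 175 and 74 were called in both fits. Without 24 h replicate 2 the fit on all arrays called 5452 and 3318, and for 72 h against 24 h it called 3857 and 4466 without 72 h replicate 3 or 4.

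The early and fading and the late patterns used the test between 72 h and 12 h, while the sustained pattern used only the calls against the controls. A sustained change can therefore also differ between times, and Slc38a5 is in both the sustained and the late pattern. Sustained changes, called in the same direction at 12, 24 and 72 h, held 537 probe sets, 293 higher and 244 lower, with Slc38a5, Fabp5, Tubb3, Rgs11 and Slc40a1 the largest. Early and fading changes, called at 12 h and called in the other direction from 12 h to 72 h, held 193, 126 higher and 67 lower at 12 h, led by Aqp5, Dmkn, Wif1, Cyp17a1 and Col4a1. Late changes, called at 72 h and called in the same direction from 12 h to 72 h, held 198, 159 higher and 39 lower, led by Drd4, Slc38a5, Rhox5, Eppin and Igfbp3. With the block the patterns held 414, 222 and 212 probe sets, of which 339, 174 and 163 were shared. Array weights gave 579 early and fading and 677 late. The F test called 8599 probe sets at any time and 3287 with the block, and without 24 h replicate 2 it called 5130.

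Across probe sets, which are not independent replicates, fold changes at 72 h and 12 h correlated at 0.71, against 0.365 for simulated unchanged groups that share the 7 controls. When the controls were split between the times, so that the real fold changes shared none, the mean correlation was 0.495 (0.265 to 0.612). Their covariance was 0.0959 against 0.0141 simulated. The correlation was 0.279 for 24 h and 12 h, against 0.33 simulated, and 0.362 for 72 h and 24 h, against 0.332 simulated. With split controls the means were 0.165 (-0.145 to 0.561) and 0.255 (-0.066 to 0.62). The covariances were 0.0493 and 0.0673, against 0.014 and 0.0141. The simulated groups held no shift between the array sets. Such a shift enters the real fold changes at 12 h and 72 h alike, and those at 24 h in the opposite direction. The simulated values therefore cannot tell how much of the unblocked correlations and covariances is shared response to FSH. With each time set against the controls of its own set of arrays the correlations were 0.69, 0.419 and 0.561. In this form 72 h and 12 h still share the controls of the spiked set, and no unchanged value was simulated for it. Among the calls at 72 h and 12 h, 553 were higher at both times and 286 lower, against 57.9 and 17.4 for independent lists. For 24 h and 12 h these were 389 and 396 against 249 and 72.4, and for 72 h and 24 h 441 and 487 against 287 and 86.7. The values for independent lists do not allow for the shared controls.

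Between 24 h and 12 h, 3 lists were shifted without a block. Cholesterol genes were lower at 24 h (11 members lower and 1 higher, also 11 and 1 adjusted over the list alone, adjusted p = 0.000743, block 6.72e-05), matrix genes were lower (10 lower and 4 higher, also 10 and 4 adjusted over the list alone, adjusted p = 0.0106, block 0.0485) and epididymal markers were higher (adjusted p = 0.0106, block 0.0517). None held with an estimated correlation (adjusted p = 0.271, 0.928 and 0.918). With the block only 3 cholesterol members and 3 matrix members were lower, with 0 higher in either list and 0 epididymal markers called. Only with the block were immediate early genes (adjusted p = 0.000673) and myoid markers (0.0388) called lower and spermatid genes (0.0485) higher at 24 h, with adjusted p of 0.217, 0.728 and 0.764 with an estimated correlation. Between 72 h and 24 h, matrix genes (adjusted p = 0.00253, block 0.00509) were higher at 72 h, and macrophage markers (0.00275, block 0.376), ribosome biogenesis (0.00958, block 0.17) and, downwards, epididymal markers (0.005, block 0.0562) were called only without the block. The adjusted p was 0.791 for each of these 4 with an estimated correlation. Only with the block were Sertoli markers (adjusted p = 0.00464) called higher and spermatid genes (0.033) lower at 72 h, with adjusted p of 0.522 and 0.902 with an estimated correlation. Between 72 h and 12 h, macrophage markers were higher at 72 h (adjusted p = 0.000342), and immediate early genes (0.000918), myoid markers (0.000702) and retinoid genes (0.00282) were lower. The block kept these 4 calls, while the adjusted p was 0.35, 0.269, 0.243 and 0.243 with an estimated correlation. The lists shifted at 12, 24 and 72 h numbered 6, 3 and 12, counts that splits of the arrays also reached (55, 73 and 8 of 100 splits), so chance is not excluded for them. At 24 h the number was 1 without 24 h replicate 2 and 5 without 24 h replicate 3 or control 6. With the block macrophage markers at 12 h (adjusted p = 0.0446) and cell cycle genes at 72 h (0.0452) were also called lower, with adjusted p of 0.397 and 0.479 with an estimated correlation.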

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

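The tests of the array set, of the Leydig cell share, of the range of values and of other testis RNA were chosen only after the results they address were seen. The splits of arrays, the spread of the array sets and the swap of control 6 were planned earlier.

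Without a block the 24 h arrays differed from those of 12 h and 72 h at 9098 and 7001 probe sets, where 72 h and 12 h differed at 423. With the block these were 198, 84 and 535, and 1.92% and 1.06% of the 24 h differences kept their call. With the block the 24 h differences also rest on the controls of each set, which raises their error. Lost calls alone therefore do not measure the part of the array set. The differences between 24 h and 12 h correlated at 0.584 across probe sets with those between the 2 sets of untreated controls, so a technical difference between array sets likely accounts for much of them. It is not the whole cause of the calls of 24 h against controls, as 32.6% of them kept call and direction with the block. The blocked count against controls was larger at 24 h (3023) than at 12 h and 72 h. Within each set alone the counts were 1356, 393 and 1612 at 12, 24 and 72 h. The 24 h fit there had 6 arrays and 4 residual degrees of freedom, against 12 and 9 in the spiked set. These counts therefore cannot test the pattern. A narrower range of values is not the whole cause of the larger blocked count at 24 h, since it was still 2521 with quantile normalisation. Residual spread was 1.22 times larger in the 24 h set, which leaves open whether spread could matter.

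Control 6 carried transcripts of maturing spermatids that the other arrays lack, with Prm1 at 12.04, Prm2 at 12.30, Tnp1 at 11.65 and Tnp2 at 12.06, against at most 3.85, 3.40, 4.49 and 2.89 elsewhere. A swap with a treated mouse is unlikely, because its mean over the 198 probe sets that rose at all 3 times was 7.77, within the 7.68 to 7.90 of the other controls and below the 8.70 to 8.89 of treated arrays. RNA of another testis fits, as 0 of the other 17 arrays had a higher mean of pachytene spermatocyte genes. A mouse with spermatids of its own might give the same values, and the test was written after the pachytene level was known, so the cause stays open. Rhox5 (5.56), Eppin (7.10) and Tsx (9.30) were above the other controls there and Inha (9.81) below them.

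Star, Cyp11a1 and Cyp17a1 rose although the FSH receptor is not known on Leydig cells. A larger share of Leydig cells was asked of the other 12 Leydig markers at 24 h with the block. Their median was -0.07, with 3 higher and 1 lower, and the largest rise was 0.81 in Fdx1. A share that raises all markers alike was therefore not seen. A smaller change in share is not excluded, since Hsd17b3 read near the floor in controls and Insl3 and Lhcgr were not analysed. The array set was first asked of all 6 rises of these genes at 12 h and 24 h, and the division below was made after seeing that 5 kept their call. Those 5 were grouped because they kept their call, so the calls themselves cannot test the array set. Against controls of the same array set Star rose by 2.535 and 2.495, Cyp17a1 by 2.86 and 4.62 and Cyp11a1 at 24 h by 4.03. A difference between the sets does not enter these folds. Within the unspiked set alone the rise of Cyp11a1 at 24 h was not called (adjusted p = 0.0827). For Cyp11a1 at 12 h the fold hardly moved with the block (2.35 ± 0.63 to 2.24 ± 0.73) while the adjusted p rose to 0.104, which is no evidence for the array set and does not exclude it. Residual luteinising hormone activity of the hormone preparation, or signals from Sertoli cells, could also act, and the cause was not tested beyond these values of -0.07 and 0.104.

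Whether chance alone could give the counts was asked by splitting the arrays anew, with 55, 73 and 8 of 100 splits reaching the list counts. The real split gave the highest count for 12 h (1640, highest other 1163), 24 h (8137, highest other 3065) and 72 h (1915, highest other 1036), rank 1 of 100, and chance can be excluded in this fit, which has no block and in which all 24 h arrays lie in 1 set. It was also the highest of 35 splits for 24 h against 12 h (9098, highest other 2981), 72 h against 24 h (7001, highest other 52) and 72 h against 12 h (423, highest other 1), although the first 2 of these follow the array sets exactly. Within the spiked set 12 h (1211, highest other 1) and 72 h (1388, highest other 2) were the highest of 35, and for 24 h within its set there are too few splits. The F test (8599, highest other 388) and the sustained (537, highest other 116), early and fading (193, highest other 1) and late patterns (198, highest other 3) were rank 1 of 100. For the list counts chance cannot be excluded: 55 of 100 splits gave at least the 6 lists of 12 h (highest other 13), 73 at least the 3 of 24 h (highest other 11) and 8 at least the 12 of 72 h (highest other 14).

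Single arrays stood apart from their group in 42 of 558 groups of values, where 27.9 would be found by chance, as chance flags about 1 in 20 groups. Control 6 held 7 of them, 72 h replicate 4 held 5 and controls 3 and 5 held 4 each. The 24 h group, with 3 arrays, was not part of this test, so the test says nothing about single arrays at 24 h. No array was left out for standing apart.

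In control 6, Hils1 (10.15), Tssk1 (7.56) and Ccna1 (6.18), genes of spermatids and spermatocytes, and the spermatid mean (8.63) were above the other controls, whose highest values were 2.55, 3.68, 3.81 and 3.16. Slc7a4 (5.21) was also higher there, and Dazl (10.76) and Myh8 (4.82) lower. In control 5 Star (6.42), Cyp11a1 (4.40) and the Leydig mean (6.49) were high, the first 2 being members of the Leydig list, and Myh6 (8.53) was high. In control 3 Aldh1a3 (5.82), Klf4 (5.38) and Ski (6.46) were low and H1f6 (3.00) high. Slc38a5 (1.65) was low and Ros1 (2.96) high in control 2, Rpl11 (12.23) low and the fat cell mean (4.85) high in control 1, and Defb15 (3.24) low in control 4.

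Among 12 h arrays, replicate 1 had high Ccna1 (3.29), Drd4 (2.65) and Kit (7.75), replicate 2 high Cldn5 (6.02) and Jam3 (8.26), replicate 3 high Clca3a1 (5.68) and Sall4 (6.20) and a low mean of G1 cyclins (5.70), and replicate 4 high Aldh1a3 (6.96), Myh6 (8.36) and Wif1 (7.16). The values of Ccna1 and Drd4 lie near the floor, where small gaps stand out. Among 72 h arrays, replicate 4 had high Cnn1 (5.98), Hs3st1 (3.23) and Sycp3 (12.33) and low Igfbp3 (5.08) and Slc40a1 (4.01), replicate 1 high Crym (2.73) and Nsdhl (7.42) and low Hsd3b1 (11.45), replicate 2 high Tssk1 (3.01) and a high mean of ribosome biogenesis (8.54), and replicate 3 low Trim35 (5.19). The groups of 4 are small, so close values in 3 mice make the remaining one stand out.

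Time differences called with and without the block stand out because the genes moved between times and not only from the controls. From 12 h to 24 h these were Rhox5 (4.03), Myh6 (-3.58), Itga9 (-3.47) and Dapk1 (-2.89), and from 24 h to 72 h Drd4 (3.63), Dapk1 (2.77), Itga9 (2.68), Cyp17a1 (-2.94) and Aqp5 (-2.62). From 12 h to 72 h they were Drd4 (5.77), Rhox5 (5.09), Eppin (4.06), Slc7a4 (3.54), Aqp5 (-3.42), Crym (-2.78), Dmkn (-2.76), Tnfrsf12a (-2.74), Cyp17a1 (-2.46), Star (-1.66) and Kitl (-0.70). The cause was not tested.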

How the results depend on the processing

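Settings were planned, except those with the batch block, those within batch, and quantile normalisation and leaving out arrays for the agreement of times, which were chosen after seeing the data. Leaving out the lowest 50% of probe sets gave 3382 calls at 24 h, 3107 for 24 h minus 12 h, 2884 for 72 h minus 24 h, 4990 at any time and 5 lists at 24 h. With quantile normalisation these were 4735, 4326 and 3386, with 56.7%, 51.8% and 46.4% higher. Of the 3382, 3107 and 2884, 27.2%, 22.3% and 79.7% were higher. Array weights gave 2875 at 72 h, 1569 for 72 h minus 12 h, 579 early and fading and 677 late. Only the compared arrays gave 3346 at 24 h. A fold of at least 1.5 gave 1043, 3038 and 1225, and 1 probe set per gene 1053 at 12 h and 4400 at 24 h. With a correlation estimated per list, 1, 0 and 0 lists were shifted, and with the batch block too 1, 0 and 0.

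The replicate block gave 2819 calls at 24 h and 4577 for 72 h minus 24 h. Whether the numbers pair the mice is not known. Deviations of same-numbered arrays from their group means correlated above 0.1 in 4 of 21 pairs (range -0.431 to 0.48). All 4 lay within the same array set. The highest were 24 h replicate 2 with control 2 (0.48) and 24 h replicate 3 with control 3 (0.305). Arrays of different number were not compared, so these values cannot decide it.

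The batch block gave 3023 at 24 h, 198 and 84 for 24 h minus 12 h and 72 h minus 24 h, 3287 at any time and an agreement of 0.561 for 72 h and 24 h. Within batch, 24 h had 393 calls and 6 lists. With quantile normalisation the batch block gave 2521, 167, 79, 3102 and 6 lists at 24 h, with trend and robust 3418, 192, 65 and 3233, and without control 6 1023 at 12 h, 3053, 123, 50 and 3151. Sdc4 turned to -0.61 and 0.67 with the batch block and with trend and robust, to -0.62 and 0.68 with quantile normalisation and to -0.62 and 0.67 without control 6. Of 209 calls of named genes the batch block kept 159 and lost 48, and 2, both of Sdc4, took the opposite sign without being called. Quantile normalisation kept 186, median centring 203, an offset 204 and trend and robust 209. Within batch 96 of 168 were kept and 72 lost. The cause of single losses was not tested.

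On other probe sets 59 of 117 calls were kept, 34 lost and 24 reversed, which here means an opposite sign whether called or not. Called in the opposite direction without a block were Itga9, Antxr1, Myh6, Ccnd2 (0.55), Aldh1a3, Cldn1 (0.10) and Rps4x, all at 24 h. Other probe sets reversed Itga9 (0.44), Antxr1 (0.26), Myh6 (0.69), Gpam (0.98), Sall4 (0.024), Elavl2 (0.017 and 0.20), Aurkb (-0.043), Cdkn1b (0.12), Ccnd2 (0.71 and 0.55), Aldh1a3 (0.30), F11r (0.079), Cldn1 (0.10 and 0.072), Timp3 (0.26), Canx (-0.037), Bmpr1a (0.018), Rps4x (0.28) and Rps18 (0.062, 0.51 and 0.13) at 24 h, Inhbb (-0.039) at 72 h and Fdps (-0.025) at 12 h. Most of these are dim, and values near the floor limit what they can show. The cause was not tested.

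Leaving out each array gave 1112 to 1720 calls at 12 h, 3910 to 9448 at 24 h, 1288 to 2159 at 72 h, 5452 to 9746 for 24 h minus 12 h, 3318 to 7808 for 72 h minus 24 h, 212 to 443 for 72 h minus 12 h and 5130 to 9336 at any time. Lists ranged over 5 to 9, 1 to 5 and 11 to 14, and agreement over 0.24 to 0.335, 0.671 to 0.736 and 0.326 to 0.415. Of 3762 refits of named genes 142 lost the call.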

Other observations

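The list tests in this part were planned, while the single genes given as examples and the counts by level were chosen only after the values were seen. Immediate early and cAMP feedback genes were not called as a list against controls 1 h after the last dose (29 measured, adjusted p = 0.57, 0.549 and 0.0886 at 12, 24 and 72 h, and 0.0483 at 72 h without control 6). Single members moved in opposite directions. Cebpd, a transcription factor, rose by 1.80 ± 0.29, 2.10 ± 0.32 and 1.64 ± 0.29, while Ier3 fell by 1.37 ± 0.23, 2.01 ± 0.25 and 1.30 ± 0.23 (n = 4, 3 and 4 against 7). Egr1, a growth response factor, was -0.43 ± 0.23 at 12 h (adjusted p = 0.357) and fell by 2.01 ± 0.25 at 24 h and 1.35 ± 0.23 at 72 h, and Klf4 fell by 1.65 ± 0.25 at 24 h. With the block Egr1 was at -2.32 ± 0.26 and Klf4 at -1.37 ± 0.27 at 24 h. Within the unspiked set alone Klf4 was not called (adjusted p = 0.169), and its other probe set gave -0.50 (adjusted p = 0.156) and 0.02 with the block. In all, 5, 3 and 3 members rose and 2, 6 and 4 fell, or 6, 3 and 3 and 2, 6 and 4 adjusted over the list alone. The mean at 12 h was 0.11 where the median was -0.01, and the median at 24 h was 0.06 where the mean was -0.23.

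Junction genes were not called as a list (16 measured, adjusted p = 0.882, 0.367 and 0.233). F11r, a tight junction protein, fell by 1.18 ± 0.13, 1.53 ± 0.15 and 0.95 ± 0.13, Cldn1 by 0.91 ± 0.17 at 24 h and 1.51 ± 0.15 at 72 h (and at 12 h, adjusted p = 1.38e-05), and Jam3 rose by 0.87 ± 0.16, 0.81 ± 0.18 and 1.06 ± 0.16. Cldn5, a claudin of endothelial and Sertoli cells, fell by 1.16 ± 0.25 at 12 h and 1.90 ± 0.28 at 24 h. Dimmer probe sets of F11r (0.08) and Cldn1 (0.10 and 0.07) did not show the fall at 24 h. Within the unspiked set alone Jam3 (adjusted p = 0.0715), Cldn5 (0.0814) and Ier3 (0.0603) were not called at 24 h.

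Fads2, a fatty acid desaturase, rose by 1.41 ± 0.13, 1.52 ± 0.14 and 1.15 ± 0.13, while its list of lipid droplet, fatty acid synthesis and oxidation genes was not called (26 measured, adjusted p = 0.07, 0.785 and 0.58). At 12 h this list was called without 12 h replicate 1 (adjusted p = 0.0118), control 2 (0.0355) or control 5 (0.0423), so single arrays decide it. Hspb1, a small heat shock protein, fell by 1.22 ± 0.16, 1.48 ± 0.17 and 1.87 ± 0.16, and its list of 12 was not called (adjusted p = 0.819 at 12 h, above 0.5 at 24 h and 0.88 at 72 h). Cidea, a lipid droplet protein, rose by 1.83 ± 0.16, 0.75 ± 0.17 and 0.93 ± 0.16, and the fat cell markers were not called as a list (11 measured, adjusted p = 0.238 at 24 h, 0.589 at 12 h and 0.411 at 72 h, and 0.0487 at 72 h without control 1). Within the unspiked set alone Cidea was not called at 24 h (adjusted p = 0.081).

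Cdkn1b, a cyclin kinase inhibitor, fell by 0.97 ± 0.18 at 12 h, 1.39 ± 0.20 at 24 h and 0.71 ± 0.18 at 72 h, the last not called with the block (adjusted p = 0.126), and another probe set gave 0.12 at 24 h. The 15 genes of G1 cyclins and inhibitors were not called as a list (adjusted p = 0.882, 0.417 and 0.88), nor were 15 ribosomal proteins (0.882, 0.477 and 0.133), 18 endothelial markers (0.574, 0.123 and 0.575) or 6 red blood cell markers (0.35, 0.315 and 0.42). Igf1 rose by 1.03 ± 0.26 at 12 h, not called with the block (adjusted p = 0.115), and by 1.78 ± 0.29 at 24 h, 2.27 with the block.

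With the block, probe sets near the floor were mostly higher at 24 h, 671 against 64 lower among those with a mean under 4, where 12 h had 46 and 57 and 72 h 53 and 61. Among those with a mean from 6 to 8, 219 were higher and 684 lower at 24 h. The interquartile range of values was 4.39 on average on the 24 h arrays and 4.61 on the unspiked controls. A compressed range on the 24 h arrays may account for part of this, although the 24 h count was still 2521 after quantile normalisation with the block.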
